A study of Mus musculus with 8 samples.

How the data were processed

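B cells were isolated from mouse spleen and their RNA was sequenced in 8 libraries, 4 from control mice and 4 from mice with a deletion of Umps in B cells (UMPS_BKO). Per the labels' protocols, RNA was extracted on columns, enriched for poly(A) RNA with oligo(dT) beads and made into libraries with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, bcl2fastq 2.20, STAR 2.5.2b, featureCounts and Subread 1.5.2 were used with the mouse genome build GRCm38. The authors deposited one table of TPM with 1 column per library, each summing to 1000000 over 49315 features. How TPM was computed, the annotation release, the strand setting and any filter are not given in the sources used here, so genes that overlap on opposite strands, and near-identical copies such as the globin genes, are uncertain. The sum of TPM includes ribosomal RNA-like and mitochondrially encoded features, so a library rich in them has lower values for every other gene.

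Each column was matched to its sample by the library name in the labels, and groups and replicate numbers came from the sample titles. Gene symbols were those of the deposited table, 174 features had no symbol, and coordinates and exon lengths came from the GENCODE M21 annotation of GRCm38, in which 49056 features had a length. TPM keeps no depth by itself. Each library's low values, multiplied by exon length, were whole multiples of a common step, and dividing by that step recovered reads. Between 90.5% and 92.8% of the low values, those under 30 reads, came out whole within 0.05 reads. In units of 1000000 reads, the recovered depth was 5.81 to 28.6 per library, and 1 read in a transcript of 1 kb was worth 0.0531 to 0.406 TPM. No count model was run on these reads, since TPM is not a count. The read recovery returned 1.00 of the true total in each simulated library.

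A gene was tested where its TPM was at least 1 in at least 4 of the 8 libraries, which left 10708 genes. Differences were fitted on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend, no covariate, two-sided, Benjamini-Hochberg adjusted p under 0.05), so fold changes are on the log2(TPM + 1) scale and understate those of low genes. Gene lists were tested with camera at its preset correlation of 0.01, over the 32 of 33 lists with at least 3 tested members. The list left out held the sex-linked genes. Camera with an estimated correlation and fry were run beside it. Values per library were compared with exact two-sided permutation tests over the 70 assignments of 4 against 4, whose smallest p is 0.0286, and adjusted over the 33 library measures tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these.

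The group of each sample, the test, the gene lists, the filter, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule named Umps, Fcgr2b and Fcer2a; up to 12 genes in each direction that passed the test with groups that did not overlap, or the 5 with the smallest p where none with a usable name passed; up to 4 members of each list with the smallest p; and Cad, Dhodh and the immunoglobulin constant regions. Antibody segments, pseudogenes and provisional symbols were counted and not named by the rule. Some genes that fit the rule are not reported here. Ighj1, A530040E14Rik and its neighbours, and the red cell genes Alas2, Slc4a1 and Epor were singled out after their values were seen, and so were the lists of hepatocyte, skeletal muscle and ribosomal RNA-like features and most of the library measures.

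The test was checked on simulated data for this comparison, with the means and spreads of the 10708 genes and known changes added. It recovered 11.2% of genes changed by a log2 fold of 2, 71.2% at 4, 91.6% at 6 and 98.4% at 8, with 5.48% of calls false, and it called a list shifted by −2 in 5 of 5 simulations. The simulated errors were independent between genes, whereas real list members varied together (estimated correlation 0.57 for germinal centre genes). The check therefore does not give the rate of false gene or list calls in these data. Other settings fixed in advance were a pseudocount of 0.1 or 5, no filter beyond a TPM above 0, a mean TPM of at least 5, removal of immunoglobulin genes, scaling by the median of ratios, quantile normalization, no trend, array weights, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were removal of ribosomal RNA-like and mitochondrial features, exclusion of the most liver- and muscle-marked libraries (control replicate 2 and UMPS_BKO replicate 4), exclusion of UMPS_BKO replicates 2, 3 and 4, and the pan-B cell mean as a covariate. A planned fit with the sex of the mice as a covariate was left out, because transcripts of both sexes were read together in some libraries and the sexes could not be assigned.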

Results

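Gene expression was measured by poly(A)-enriched RNA sequencing in B cells isolated from the spleens of mice that were 4 months old. All mice lacked FcγRIIB, the inhibitory Fc receptor encoded by Fcgr2b, a background in which mice develop a spontaneous disease resembling lupus. The 4 control samples came from mice that carried the CD23-Cre transgene alone, and the 4 UMPS_BKO samples from mice whose B cells lacked Umps. This gene encodes the enzyme that makes uridine monophosphate in the last steps of de novo pyrimidine synthesis. The samples are numbered as replicates and nothing says that each came from a separate animal, so p-values measure only the spread between these samples, which may be technical. Each library was deposited as TPM and summed to 1000000. In units of 1000000 reads, the depth recovered from the steps between low TPM values was 14.9, 13.4, 5.81 and 18.8 in control replicates 1 to 4. It was 28.6, 10.6, 17.6 and 27.3 in UMPS_BKO replicates 1 to 4. The numbers of features above 0 were 11034, 15889, 12962 and 13027 in the controls and 13051, 8626, 10539 and 12913 in UMPS_BKO.

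The libraries differed widely in composition within each group. Ribosomal RNA-like features took 60.0%, 5.39%, 10.5% and 35.1% of TPM in control replicates 1 to 4, and 44.4%, 60.1%, 48.0% and 37.3% in UMPS_BKO replicates 1 to 4 (exact permutation p = 0.2). TPM divides reads by feature length, so short features weigh more in TPM than in reads. Of recovered reads these features took 15.4%, 0.543%, 1.02% and 5.22% in the controls and 7.49%, 18.0%, 13.7% and 8.70% in UMPS_BKO (exact permutation p = 0.171). Mitochondrially encoded transcripts took 9.12%, 8.22%, 5.33% and 8.88% in the controls and 8.42%, 19.2%, 18.5% and 17.2% in UMPS_BKO (exact permutation p = 0.0857). Hepatocyte transcripts reached 5.57% of TPM in control replicate 2 and 1.71% in control replicate 3, and skeletal muscle transcripts 16.2% in UMPS_BKO replicate 4. Whether these came from tissue in the isolates or were carried over from other libraries was not tested. The mean log2(TPM + 1) of 16 pan-B cell genes was 7.16, 8.12, 8.62 and 8.07 in the controls and 7.87, 6.16, 6.64 and 4.57 in UMPS_BKO (exact permutation p = 0.0571). The median log2 fold change of all tested genes was −0.90 on the TPM scale, −0.15 after scaling by the median of ratios and −0.02 after quantile normalization. Groups of genes are therefore given relative to the other tested genes. For members of gene lists named with a log2 difference alone, the difference after scaling by the median of ratios follows in brackets.

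**Figure D1:**
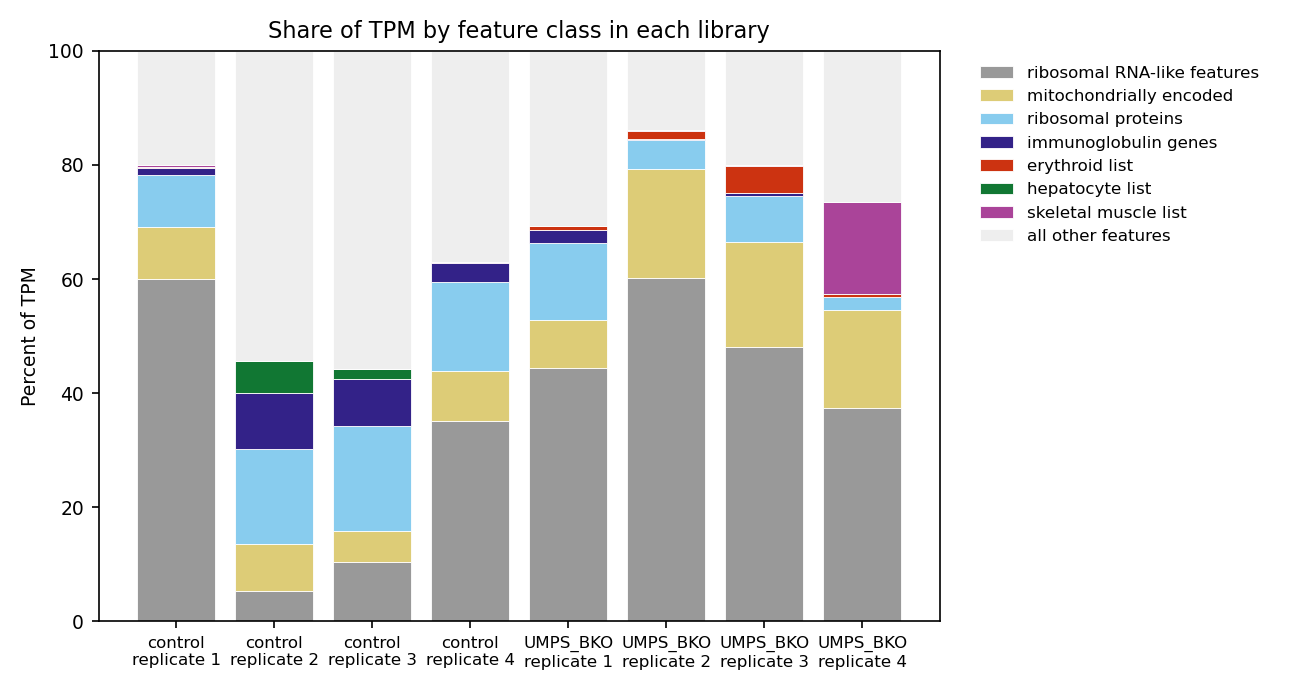
Stacked bars show the percent of TPM (y axis, from 0) taken by each class of features in each of the 8 libraries (x axis). The hepatocyte list is visible in control replicates 2 (5.57%) and 3 (1.71%), the skeletal muscle list in UMPS_BKO replicate 4 (16.2%), and the erythroid list reaches 4.79% in UMPS_BKO replicate 3.

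The comparison asks how the transcriptional state of B cells differs when Umps is deleted in them. The deleted gene Umps (ENSMUSG00000022814, GRCm38 chromosome 16, 33954782 to 33967038, minus strand) was at 16.1, 35.1, 18.6 and 8.98 TPM in the controls and at 5.99, 1.05, 13.6 and 2.16 TPM in UMPS_BKO. Red cell genes such as Hbb-bs rose in UMPS_BKO (log2 difference 5.25 ± 0.77, SE, n = 4 per group; limma, adjusted p = 0.0215). Antibody segments fell, with Ighj1 listed at 0 in all 4 UMPS_BKO libraries (limma, adjusted p = 0.000243). Germinal centre B cell genes fell as a group, at −1.41 relative to the other tested genes (camera, adjusted p = 7.71e-07; adjusted p = 0.784 with an estimated correlation).

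For Umps the groups overlapped, because UMPS_BKO replicate 3 lay above control replicate 4, and the log2 difference of −1.88 ± 0.76 (SE, n = 4 per group) did not pass the test (limma, adjusted p = 0.283). After scaling by the median of ratios it was −1.10. The Umps values rested on 711, 713, 160 and 339 recovered reads in the controls and 393, 36, 629 and 119 in UMPS_BKO. Which exons the deletion removes is not given in the sources used here, and reads outside them do not test the labels. Fcgr2b, the gene inactivated in every mouse, was still read at 11.9 ± 3.76 TPM in the controls and 4.10 ± 3.63 TPM in UMPS_BKO (SD, n = 4 each). Fcer2a, which encodes CD23 and whose promoter drives Cre, was at 263 ± 125 TPM in the controls and 91.7 ± 96.9 TPM in UMPS_BKO (SD, n = 4 each). Neither gene passed the test (limma, adjusted p = 0.283 for each).

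Transcripts of red blood cells were higher in UMPS_BKO. The globin genes Hbb-bs, Hba-a1 and Hbb-bt were among the 4 genes that rose of 10708 tested. Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) was at 198, 195, 61.3 and 81.9 TPM in the controls and at 2582, 5148, 19521 and 1639 TPM in UMPS_BKO. The log2 difference was 5.25 ± 0.77 (SE; limma, adjusted p = 0.0215), with 4 of 4 UMPS_BKO libraries above all controls. Hba-a1 differed by 5.17 ± 0.78 (adjusted p = 0.0215) and Hbb-bt by 5.55 ± 0.87 (adjusted p = 0.0288), with 4 of 4 libraries above all controls for each. Hba-a2, at 6.28 ± 1.12, did not pass (adjusted p = 0.0699), and passed without UMPS_BKO replicate 1 (adjusted p = 0.0282). With all libraries kept, it passed in limma with a pseudocount of 5, array weights or the replicate block (adjusted p = 0.0241, 0.0249 and 0.0195). Hba-a1 and Hba-a2 are near-identical copies, as are parts of Hbb-bs and Hbb-bt, so the division of reads within each pair is uncertain.

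Of the 18 erythroid genes tested, 3 rose over all genes and 9 when adjusted over the list alone. The list lay 3.59 log2 units above the other tested genes (camera, adjusted p = 3.84e-34; adjusted p = 0.104 with an estimated correlation). Its share of TPM was 0.0522%, 0.0639%, 0.0241% and 0.0277% in the controls against 0.599%, 1.35%, 4.79% and 0.431% in UMPS_BKO. This was a 29.4-fold difference in geometric means (exact permutation p = 0.0286, the smallest that 70 assignments allow; adjusted p = 0.157 over 33 library measures). On the log2 scale the difference was 4.88, and 4.18 without UMPS_BKO replicate 3. The 7 platelet and megakaryocyte genes lay 1.58 above the other genes (camera, adjusted p = 2.74e-05; adjusted p = 0.104 with an estimated correlation), with none called singly over all genes or adjusted over the list alone. Their members Pf4, Clec1b and Ppbp had log2 differences of 1.46 (2.15), 1.24 (1.62) and 1.05 (1.98), and Ppbp turned to −1.24 when UMPS_BKO replicates 2, 3 and 4 were left out. The 24 mitochondrially encoded transcripts lay 1.37 above the other genes (camera, adjusted p = 3.07e-15; adjusted p = 0.209 with an estimated correlation). The transcripts mt-Tv, mt-Co3 and mt-Te stood at 2.2 (3.15), 1.54 (2.28) and 1.48 (2.44) and mt-Ty at −2.93 (−2.14), and 0 were called over all genes or adjusted over the list alone in limma. The transcripts mt-Tv and mt-Ty passed with array weights, and mt-Tv without UMPS_BKO replicate 1 (adjusted p = 0.0292). The platelet and mitochondrial calls ended without UMPS_BKO replicates 2, 3 and 4 (0.18, adjusted p = 0.477, and 0.12, adjusted p = 0.109). The call of all 4 single genes ended when control replicate 3, control replicate 4, UMPS_BKO replicate 2 or UMPS_BKO replicate 3 was left out, with 0 genes higher in each case. For Hbb-bs the log2 difference was then 4.94, 5.08, 5.19 and 4.55 and the adjusted p 0.0917, 0.0766, 0.118 and 0.0586, in a range of 0.00486 to 1.00 over all settings. It was 0.0516 with a pseudocount of 0.1 (log2 difference 5.26), 0.334 with no filter (5.25) and 0.0742 without ribosomal RNA-like and mitochondrial features (6.03). Camera with its preset correlation called the erythroid list in each of 22 alternative settings.

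Antibody transcripts were lower in UMPS_BKO. Of the 10 genes that fell, 8 were immunoglobulin variable or joining segments and the other two had provisional symbols. The heavy chain joining segment Ighj1, singled out after its values were seen, averaged 235 ± 137 TPM in the controls (SD, n = 4). Over this short segment (GRCm38 chromosome 12, 113429781 to 113429833) the values rested on 71, 102, 49 and 75 recovered reads in control replicates 1 to 4. Ighj1 was listed at 0 in all 4 UMPS_BKO libraries (limma, adjusted p = 0.000243). Of 120 variable segments tested, 7 fell over all genes and 71 when adjusted over the list alone. The list lay at −2.95 relative to the other genes (camera, adjusted p = 1.37e-23; adjusted p = 0.784 with an estimated correlation). Of 11 constant region genes, 0 passed over all genes in limma and 10 fell when adjusted over the list alone (list at −2.96; camera, adjusted p = 8.39e-08; adjusted p = 0.771 with an estimated correlation). All immunoglobulin genes together took 5.62% ± 4.05 of TPM in the controls and 0.781% ± 1.00 in UMPS_BKO (SD, n = 4 each; exact permutation p = 0.0571). The p became 0.0286 in the exact test without control replicate 1 (difference −6.29 percentage points). Erythroid share was higher and the pan-B cell mean lower in the same UMPS_BKO libraries, replicate 1 being the exception for the pan-B cell mean.

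The constant regions of the IgG classes differed more than that of IgM. Ighg2c, the most abundant of them in the controls, was at 216, 6877, 3268 and 396 TPM in the controls and at 172, 0, 6.19 and 4.67 TPM in UMPS_BKO. Its log2 difference was −7.01 ± 1.43 (adjusted p = 0.118). Ighg1 differed by −5.43 ± 1.02 (adjusted p = 0.0899), Ighg2b by −5.24 ± 1.04 (adjusted p = 0.114) and Ighg3 by −5.35 ± 1.17 (adjusted p = 0.144). For each of these 4 genes all UMPS_BKO libraries lay below all controls, and none passed the test over all genes in limma with all libraries. Without UMPS_BKO replicate 1 all 4 passed (adjusted p = 0.00473 for Ighg1, 0.00796 for Ighg2b, 0.00719 for Ighg2c and 0.0344 for Ighg3), as they did with array weights or with the replicate number as a block. Over all settings their adjusted p ranged from 0.00473, 0.00681, 0.00719 and 0.0212 to 1.00. Ighm differed by −2.65 ± 0.89 (adjusted p = 0.283), Ighd by −2.23 ± 0.83 (adjusted p = 0.283) and Igha by −2.08 ± 1.05 (adjusted p = 0.297). The κ light chain Igkc differed by −4.06 ± 1.11 (adjusted p = 0.277) and the λ light chain Iglc1 by −3.05 ± 0.90 (adjusted p = 0.283). Ighm, Igkc and Iglc1 passed without UMPS_BKO replicate 1 (adjusted p = 0.0346, 0.0222 and 0.0346). After scaling by the median of ratios the differences were −6.33 for Ighg2c, −4.88 for Ighg1, −4.36 for Ighg2b and −4.70 for Ighg3. They were then −1.69 for Ighm, −1.28 for Ighd, −1.14 for Igha, −3.10 for Igkc and −2.11 for Iglc1. Igha turned to 0.62 without UMPS_BKO replicates 2, 3 and 4 and to 0.68 with the pan-B cell mean as covariate. Expressed per 100 TPM of Ighm, the summed IgG genes stood at 34.8, 219, 85.1 and 19.4 in the controls and at 8.61, 1.73, 5.92 and 7.21 in UMPS_BKO. This was a fold of 0.0843 (exact permutation p = 0.0286, adjusted p = 0.157 over 33 library measures), lower in 4 of 4 libraries. On the log2 scale the difference was −3.57, and −2.94 without control replicate 2. The exact p became 0.0571 without UMPS_BKO replicate 2 (−3.05), 3 (−3.65) or 4 (−3.74). Igha per 100 TPM of Ighm had overlapping groups (fold 1.44, exact permutation p = 0.457).

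**Figure D2:**
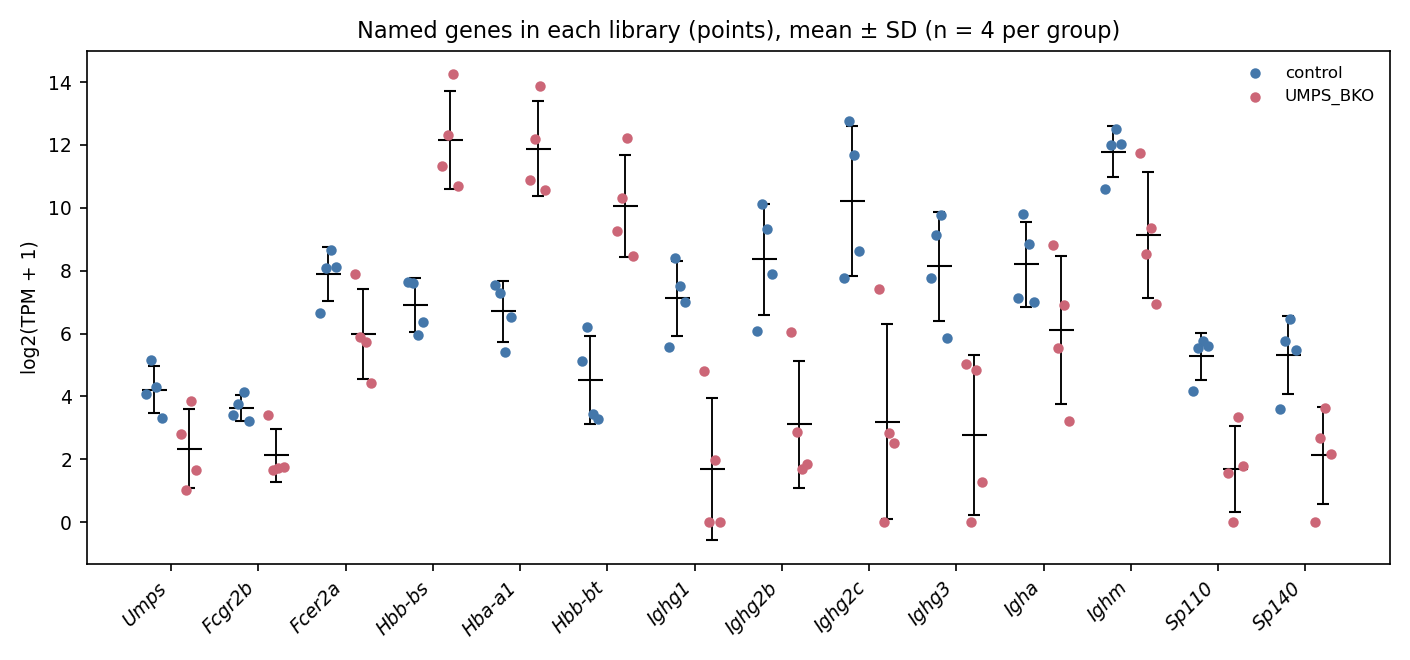
Points show log2(TPM + 1) (y axis) of 14 genes (x axis) in the 4 control and 4 UMPS_BKO libraries, with the mean and SD of each group as bars (n = 4). Hbb-bs, Hba-a1 and Hbb-bt lie higher in all 4 UMPS_BKO libraries, the 4 IgG genes lie lower in all 4, and Umps overlaps between the groups.

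Genes of germinal centre B cells, the activated cells that mutate and select their antibody genes, fell as a group. None of the 20 tested members passed over all genes in limma, and 11 fell when adjusted over the list alone. The list lay at −1.41 relative to the other genes (camera, adjusted p = 7.71e-07; adjusted p = 0.784 with an estimated correlation). Gcsam stood at 2.53 to 45.7 TPM in the controls and at 1.63 TPM in UMPS_BKO replicate 1 and 0 in the others (adjusted p = 0.152). Mef2b, a transcription factor upstream of Bcl6, and Rassf6 were listed at 0 in all UMPS_BKO libraries and reached 11.8 and 7.70 TPM in control replicate 2. Relative to the pan-B cell mean of each library, the germinal centre mean differed by −0.58 log2 units with overlapping groups (exact permutation p = 0.371). It stood at −5.21, −5.15 and −4.94 in UMPS_BKO replicates 1 to 3, below the controls (−4.84 to −3.16), and at −2.98 in the muscle-marked replicate 4. In replicate 4 the pan-B cell mean was 4.57 and a list mean cannot fall below 0. Its value could therefore not have reached the −4.84 of control replicate 1. The overlap with all libraries was thus fixed by this floor and cannot speak against a lower germinal centre mean. Without replicate 4 the difference was −1.11 (exact permutation p = 0.0571). It was −0.31 without control replicate 2, −0.37 without UMPS_BKO replicate 1, and −0.86 without control replicate 1 (exact permutation p = 0.714, 0.571 and 0.286). Removing ribosomal RNA-like and mitochondrial features gave −1.25, and leaving out the liver- and muscle-marked libraries gave −0.83 (exact permutation p = 0.2 and 0.1). With those libraries left out the groups did not overlap, and 0.1 is the smallest p that the exact test then allows. Leaving aside antibody segments and provisional symbols, no gene was called lower in limma. Among the 5 smallest p-values were those of Chst1 (−3.85 ± 0.72, adjusted p = 0.0899), a sulfotransferase gene, of Ighg1 and Ighg2b, and of Ift22 (−3.30 ± 0.66, adjusted p = 0.114). For each of these genes the 4 UMPS_BKO libraries lay below the controls. After scaling by the median of ratios Chst1 stood at −3.36 and Ift22 at −2.75. Leaving out control replicate 1 brought Chst1, Ift22 and Ighg2b (adjusted p = 0.0444 for each) and Gcsam (adjusted p = 0.0356) past the threshold. Leaving out UMPS_BKO replicate 1 did so for Chst1 (adjusted p = 0.0297), Ift22 and Gcsam (adjusted p = 0.0444 for each). Over all settings the adjusted p ranged from 0.0117 for Chst1 and Ift22 and 0.00941 for Gcsam to 1.00.

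Plasma cell genes lay at −0.92 relative to the other genes (23 tested; 0 called over all genes in limma, 11 lower when adjusted over the list alone; camera, adjusted p = 0.00239; adjusted p = 0.878 with an estimated correlation). Relative to the pan-B cell mean of each library, the plasma cell mean differed by −0.10 log2 units with overlapping groups (exact permutation p = 0.8). This mean stood at −4.08, −4.49 and −4.11 in UMPS_BKO replicates 1 to 3, below the controls (−4.00 to −3.07), and at −2.46 in the muscle-marked replicate 4. The list's call ended with the pan-B cell mean as covariate (−0.35, adjusted p = 0.106) and without UMPS_BKO replicates 2, 3 and 4 (−0.24, adjusted p = 0.355). Sdc1, the surface marker CD138, was at 4.90 to 44.2 TPM in the controls and at 4.75 TPM in UMPS_BKO replicate 1 and 0 in the others (adjusted p = 0.254). The secretory pathway genes Derl3, Fkbp11 and Txndc5 had log2 differences of −3.15 (−2.70), −3.08 (−2.61) and −2.87 (−1.96). The 30 genes of endoplasmic reticulum stress and secretion lay at −0.56 (0 called over all genes or adjusted over the list alone in limma; camera, adjusted p = 0.00137; adjusted p = 0.878 with an estimated correlation). That call ended with the covariate (−0.07, adjusted p = 0.522), without UMPS_BKO replicates 2, 3 and 4 (−0.08, adjusted p = 0.419) and without the liver- and muscle-marked libraries (−0.31, adjusted p = 0.0682). Among its genes Manf stood at −2.47 (−1.54) and Pdia6 at −1.98 (−1.05). Follicular and naive B cell genes lay at −0.95 (20 tested; 0 over all genes, 11 lower when adjusted over the list alone; camera, adjusted p = 0.00155; adjusted p = 0.878 with an estimated correlation). Il4ra stood at −3.32 (−2.59), Btla at −2.70 (−1.80) and Ccr7 at −2.33 (−1.41). Without UMPS_BKO replicate 4, the muscle-marked library with the lowest pan-B cell mean, the follicular list lay at −0.31 (adjusted p = 0.173). It turned to 0.36 with the covariate and to 0.21 without UMPS_BKO replicates 2, 3 and 4 (adjusted p = 0.191 and 0.355). Relative to the pan-B cell mean the follicular mean differed by −0.12 (exact permutation p = 0.314). Pan-B cell genes lay at −0.83 (16 tested; 0 over all genes, 8 lower when adjusted over the list alone; camera, adjusted p = 0.0107; adjusted p = 0.878 with an estimated correlation). Fcmr stood at −3.22 (−2.27), Cd79a at −2.75 (−1.79) and Spib at −2.54 (−1.60). That call ended without control replicate 1 (adjusted p = 0.0652) or UMPS_BKO replicate 4 (−0.21, adjusted p = 0.362) and without the liver- and muscle-marked libraries (−0.32, adjusted p = 0.160). The list turned to 0.15 without UMPS_BKO replicates 2, 3 and 4 (adjusted p = 0.597), and the pan-B cell and follicular calls ended with array weights (adjusted p = 0.0996 and 0.0625). Age-associated B cell genes lay at −0.65 (21 tested; 0 over all genes, 1 lower when adjusted over the list alone; camera, adjusted p = 0.0328; adjusted p = 0.878 with an estimated correlation). S100a6 stood at −2.73 (−2.02) and Fcrl5 at −2.78 (−2.24). That call ended without control replicate 1 (adjusted p = 0.0712) or UMPS_BKO replicate 4 (−0.40, adjusted p = 0.229), with a mean TPM of at least 5 (adjusted p = 0.0534) and with array weights (adjusted p = 0.158). It also ended with the covariate (−0.09, adjusted p = 0.522), without the liver- and muscle-marked libraries (−0.38, adjusted p = 0.205) and without UMPS_BKO replicates 2, 3 and 4 (−0.13, adjusted p = 0.430). Without UMPS_BKO replicate 1, limma called Sdc1, Fkbp11, Txndc5, Manf, Il4ra, Btla, Ccr7, Fcmr, Cd79a, Spib and S100a6 lower (adjusted p = 0.0171 to 0.0444). Marginal zone and B1 B cell genes (17 tested, −0.32, adjusted p = 0.184) and B cell activation genes (24 tested, −0.53, adjusted p = 0.0736) were not called by camera and held 0 genes called over all genes or adjusted over the list alone in limma. The activation list passed without UMPS_BKO replicate 1 (adjusted p = 0.0274), replicate 2 (adjusted p = 0.0225) or replicate 3 (adjusted p = 0.0443), with no filter (adjusted p = 0.00560), with quantile normalization (adjusted p = 0.0360) and with the replicate block (adjusted p = 0.0462). It turned to 0.33 with the covariate (camera, adjusted p = 0.0631) and to 0.15 without UMPS_BKO replicates 2, 3 and 4. The marginal zone list passed with no filter (adjusted p = 0.0336).

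In the pathway of the deleted enzyme, the 17 tested genes of de novo pyrimidine and dTTP synthesis lay at −0.72 relative to the other genes (camera, adjusted p = 0.0201; adjusted p = 0.878 with an estimated correlation), with 0 genes called over all genes or adjusted over the list alone in limma. Cad, which catalyses the first steps, was at 12.3 ± 8.15 TPM in the controls and 3.48 ± 1.93 TPM in UMPS_BKO (SD, n = 4 each; limma, adjusted p = 0.348). Dhodh, the mitochondrial enzyme before Umps, had a difference of −0.14 ± 0.78 (adjusted p = 0.917). It turned to 0.45 after scaling by the median of ratios, to 0.76 after quantile normalization, to 0.08 without control replicate 2, to 0.02 without control replicate 3 and to 0.52 without UMPS_BKO replicate 2. Dtymk stood at −1.97 (−1.11) and Rrm2 at −2.28 (−1.61). The list's call ended without UMPS_BKO replicate 1 (adjusted p = 0.0635) or replicate 4 (adjusted p = 0.0819) and with array weights (adjusted p = 0.137). It also ended with the pan-B cell mean as covariate (−0.42, adjusted p = 0.190) and without the liver- and muscle-marked libraries (−0.56, adjusted p = 0.128). Genes of UDP-sugar synthesis and glycosylation, which use uridine nucleotides, lay at −0.59 (26 tested). In limma 0 were called over all genes and 2 were lower when adjusted over the list alone (camera, adjusted p = 0.0168; adjusted p = 0.878 with an estimated correlation). Among them were Galk1 at −3.79 (−3.08) and Pgm3 at −2.05 (−1.67), and Galk1 passed without UMPS_BKO replicate 1 (adjusted p = 0.0339). The list's call ended without UMPS_BKO replicate 3 (adjusted p = 0.0671) and with a mean TPM of at least 5 (adjusted p = 0.104), and was kept in 17 of 22 settings. It also ended with the covariate (−0.38, adjusted p = 0.0731), without the liver- and muscle-marked libraries (−0.51, adjusted p = 0.0537) and without UMPS_BKO replicates 2, 3 and 4 (−0.23, adjusted p = 0.225). Pyrimidine salvage, transport and breakdown (15 tested, −0.42, adjusted p = 0.271) was not called by camera, with 0 genes adjusted over the list alone in limma. Purine synthesis and salvage (19 tested, −0.44, adjusted p = 0.118) was not called either, with 1 gene lower when adjusted over the list alone, and passed without control replicate 1 (adjusted p = 0.0428). Both lists passed with no filter (adjusted p = 0.0336 and 0.00620). The pan-B cell mean and the immunoglobulin share were lower in the same 3 UMPS_BKO libraries, replicates 2, 3 and 4.

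Ribosomal protein genes lay at −0.52 relative to the other genes (85 tested, 0 called over all genes or adjusted over the list alone in limma; camera, adjusted p = 8.39e-08; adjusted p = 0.878 with an estimated correlation). Rpl28 stood at −2.01 (−1.06) and Rps28 at −1.86 (−0.91). S phase genes lay at −0.44 (29 tested; 0 over all genes or adjusted over the list alone; camera, adjusted p = 0.0426; adjusted p = 0.878 with an estimated correlation). Cdc45 stood at −2.69 (−2.12) and Dscc1 at −1.74 (−1.44). The S phase call ended without control replicate 2 (adjusted p = 0.109) and without UMPS_BKO replicate 1 (0.243), replicate 2 (0.0601) or replicate 4 (0.568). It also ended with a pseudocount of 0.1 (0.0737), a mean TPM of at least 5 (0.113), array weights (0.582), the liver- and muscle-marked libraries left out (0.797) and the pan-B cell mean as covariate (0.997). With that covariate the ribosomal protein list turned to 0.30 (adjusted p = 0.0809). G2/M genes (27 tested, −0.46, adjusted p = 0.145) were not called by camera. They passed without control replicate 1 (adjusted p = 0.0414) or UMPS_BKO replicate 3 (−0.99, adjusted p = 2.45e-05). They also passed with no filter (0.0198), with the median of ratios (0.0456) and with quantile normalization (0.0405). Without UMPS_BKO replicates 2, 3 and 4 together they lay at −0.86. They turned to 0.009 without the liver- and muscle-marked libraries (adjusted p = 0.807) and to 0.048 with the pan-B cell mean as covariate (adjusted p = 0.965). Camera called none of the lists for MYC targets and ribosome biogenesis (30 tested, adjusted p = 0.618), p53 targets (23, adjusted p = 0.957), or the integrated stress response (21, adjusted p = 0.444). The MYC list passed with no filter (adjusted p = 0.0409). Nor did it call immediate early genes (18, adjusted p = 0.484), glycolysis (20, adjusted p = 0.444) or oxidative phosphorylation (34, adjusted p = 0.929). Without UMPS_BKO replicate 4 the oxidative phosphorylation list moved from 0.02 to −0.58 (adjusted p = 0.000152). The type I interferon list was not called (29 tested, −0.23, adjusted p = 0.553). With the pan-B cell mean as covariate the list turned to 0.68 (camera, adjusted p = 0.00129). Its member Rsad2 lay above all controls in 4 of 4 UMPS_BKO libraries (15.2 to 189 TPM against 4.41 to 9.76 TPM; log2 difference 2.65 ± 0.75, adjusted p = 0.277; 3.48 after scaling by the median of ratios). Its members Ifit3 at −2.96 (−2.31), Ly6c2 at −2.66 (−1.94) and Zbp1 at −2.55 (−1.90) went the other way with overlapping groups (adjusted p = 0.283 for each), and Ifit3 passed without UMPS_BKO replicate 1 (adjusted p = 0.0325). With array weights Ifit3, Ly6c2 and Zbp1 passed too as lower, and Rsad2 passed as higher (3.25; limma, adjusted p = 0.0280). Ifit3 turned to 0.16 without UMPS_BKO replicates 2, 3 and 4. In UMPS_BKO replicates 1 to 4 Rsad2 was at 30.8, 43.0, 189 and 15.2 TPM. The globin gene Hbb-bs had the same order there (2582, 5148, 19521 and 1639 TPM). Whether the rise of Rsad2 goes with the interferon response or with the red cell transcripts was not tested. Markers of other cells were not called for T cells (15 tested, adjusted p = 0.223), NK cells (9, adjusted p = 0.929) or monocytes, macrophages and neutrophils (24, adjusted p = 0.549). Nor were they called for dendritic cells (4, adjusted p = 0.655) or stromal and endothelial cells (8, adjusted p = 0.442). The T cell list passed without UMPS_BKO replicate 3 (−0.67, adjusted p = 0.0383). With the pan-B cell mean as covariate, camera called monocytes, macrophages and neutrophils higher (0.78, adjusted p = 0.000348) and stromal and endothelial cells lower (−1.06, adjusted p = 0.0432). Without UMPS_BKO replicates 2, 3 and 4 the NK cell list lay at 0.80 and the stromal list at −1.08. None of these lists, G2/M genes included, had a gene called over all genes or adjusted over the list alone in limma.

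**Figure D3:**
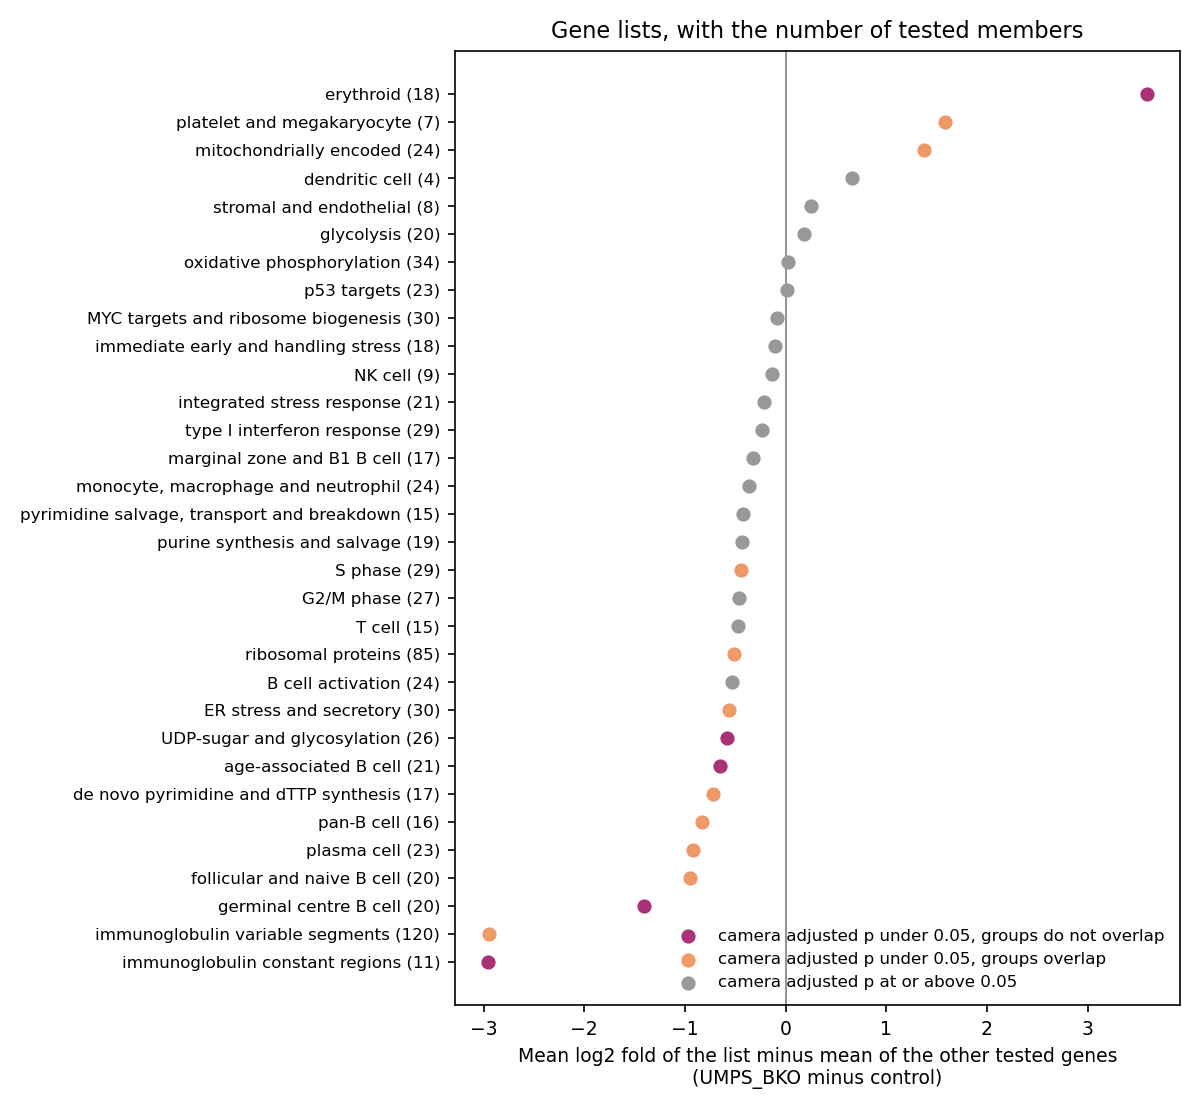
Each point is the mean log2 fold change of a gene list minus that of the other tested genes (x axis, UMPS_BKO minus control) for the 32 lists tested (y axis, number of tested members in brackets), coloured by whether camera called the list and whether the libraries of the groups overlap. The erythroid list lies at 3.59, and the immunoglobulin lists lie at −2.95 and −2.96.

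In all, 4 genes were higher and 10 lower in UMPS_BKO (limma, adjusted), while 1859 genes had an unadjusted p under 0.05, of which 99 were higher and 1760 lower. The number at an unadjusted p under 0.05 was 847 after scaling by the median of ratios and 917 after quantile normalization. The 4 UMPS_BKO values lay above all controls for 54 genes and below all controls for 515, together 5.31% of tested genes where chance gives 2.86%. Chance gives the same share in each direction, so only the genes below all controls exceeded it. That is the direction of the median log2 fold of all tested genes (−0.90), and these counts were not repeated after scaling. Camera called 15 of 32 lists, 3 higher and 12 lower, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). At the preset correlation, other splits of the 8 libraries into 4 and 4 gave a median of 11 called lists. Fry, which asks whether the genes of a list move one way, called 0 as well (9 at an unadjusted p under 0.05). Of the 15 lists, 9 were called without control replicate 2 and UMPS_BKO replicate 4 together, 6 without UMPS_BKO replicates 2, 3 and 4 together and 6 with the pan-B cell mean as covariate. Where limma called 0 single genes of a list that camera called, the genes at an unadjusted p under 0.05 numbered 10 constant region, 3 mitochondrial, 43 ribosomal protein, 12 germinal centre and 0 platelet genes. They further numbered 11 secretory, 13 follicular, 14 plasma cell, 10 pan-B cell, 8 UDP-sugar, 5 pyrimidine synthesis, 11 age-associated and 8 S phase genes. The counts of higher and lower genes were 4 and 6 after scaling by the median of ratios, 4 and 5 after quantile normalization, and 4 and 2 without immunoglobulin genes. They were 1 and 5 without ribosomal RNA-like and mitochondrial features. Leaving out single libraries gave 6 and 24 (control replicate 1), 4 and 6 (control replicate 2) and 0 and 1 (control replicate 3 or 4, UMPS_BKO replicate 2 or 3). They were 17 and 231 (UMPS_BKO replicate 1) and 4 and 3 (UMPS_BKO replicate 4).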

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

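Among 198 groups of 4 libraries examined for a value far from the others, 15 held one. For independent values with a normal spread the rate is about 1 in 20, or 9.9. That rate does not hold here, because genes varied together. Where the other values are all 0, as for Chst1 and Cdc45 in UMPS_BKO, any value above 0 is flagged. The genes examined are those named in the text, and most of the library measures among them were chosen after the data were seen.

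UMPS_BKO replicate 1 stood apart from the other UMPS_BKO libraries for several B cell genes. It was the only UMPS_BKO library with reads of Chst1 (1.43 TPM), Gcsam (1.63 TPM), Sdc1 (4.75 TPM), Derl3 (4.53 TPM), Fkbp11 (5.45 TPM) and Pgm3 (1.18 TPM), which were listed at 0 in the others. It also held 149 variable segments above 0, against 14 to 37 in the others, and Fcgr2b at 9.54 TPM against 2.18 to 2.40 TPM. In UMPS_BKO replicate 4, Cdc45 was at 0.758 TPM and at 0 in the others, and the germinal centre mean relative to the pan-B cell mean was −2.98 log2 units against −5.21 to −4.94. In UMPS_BKO replicate 3, Slc4a1, the red cell anion exchanger, was at 197 TPM against 9.52 to 10.5 TPM.

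In control replicate 1, Fcrl5 was at 9.17 TPM against 21.6 to 24.8 TPM in the other controls, Sp110 at 17.1 TPM against 46.0 to 53.2 TPM and Sp100 at 33.4 TPM against 90.8 to 101 TPM. In control replicate 3, Hba-a2 was at 0.608 TPM against 34.7 to 64.6 TPM.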

How the results depend on the processing

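The settings that remove ribosomal RNA-like and mitochondrial features, leave out the liver- and muscle-marked libraries, leave out UMPS_BKO replicates 2, 3 and 4, or add the pan-B cell mean were chosen after the data were seen, and the others were planned. The direction of Umps was the same in all 22 settings (−2.39 to −0.97), and it passed the test in none. With all libraries its difference of −1.88 was close to that of the pan-B cell mean (−1.68), so the direction alone does not test the deletion. Against 4 genes higher and 10 lower, the counts were 1 and 7 with pseudocount 0.1, 5 and 5 with pseudocount 5, 0 and 1 with no filter (19860 genes tested), 4 and 6 with a mean TPM of at least 5, 4 and 2 without immunoglobulin genes, 4 and 6 with the median of ratios, 4 and 5 with quantile normalization, 84 and 1906 with array weights, 1 and 5 without ribosomal RNA-like and mitochondrial features, 3 and 1 without the liver- and muscle-marked libraries, 0 and 0 with UMPS_BKO replicate 1 alone against the controls (102 genes at an unadjusted p under 0.05 in limma, the lone library being assumed to vary like the controls) and 0 and 1 with the pan-B cell mean as covariate. Fewer genes or libraries entered where immunoglobulin genes or libraries were left out. For the other changes the cause was not tested. Leaving out single libraries gave 0 to 17 higher genes (17 without UMPS_BKO replicate 1) and 1 to 231 lower genes (231 without UMPS_BKO replicate 1). With the replicate number as a block, 5 genes were higher and 23 lower, with 11 of the 14 calls shared. Same-numbered libraries did not deviate together (correlations −0.35, −0.19, −0.03 and −0.09, none the best partner). These correlations cannot exclude a pairing, because composition differed widely between the libraries. Camera called 10 to 22 lists over the settings, 0 with an estimated correlation and 0 by fry. The difference in the immunoglobulin share of TPM ranged over single libraries left out from −6.29 (without control replicate 1) to −3.43 percentage points (without control replicate 2). It was −2.89 for constant region genes only, −5.77 without ribosomal RNA-like and mitochondrial features and −3.19 without the liver- and muscle-marked libraries.

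List means relative to other genes that turned direction and were called by camera before or after the change were these, and the cause was not tested. Oxidative phosphorylation (0.02) moved to −0.51 without the liver- and muscle-marked libraries, to −0.27 without UMPS_BKO replicates 2, 3 and 4, to −0.84 with the pan-B cell mean, and between −0.58 (without UMPS_BKO replicate 4) and 0.32 (without UMPS_BKO replicate 2) over single libraries left out. Without UMPS_BKO replicates 2, 3 and 4, the follicular list lay at 0.21, interferon at 0.39, pan-B cell at 0.15, NK cell at 0.80, stromal at −1.08 and ribosomal proteins at 0.15. With the pan-B cell mean as covariate, the follicular list lay at 0.36, S phase at 0.045, interferon at 0.68, monocyte, macrophage and neutrophil at 0.78, stromal at −1.06 and ribosomal proteins at 0.30. With no call on either side, direction turned in 10 of 22 settings for p53 targets, 8 for MYC targets, 6 each for oxidative phosphorylation, NK cell and glycolysis and 3 each for interferon, stromal and monocyte, macrophage and neutrophil lists. It did so in 2 each for G2/M, pyrimidine salvage, marginal zone, B cell activation and T cell lists and in 1 each for immediate early and dendritic cell lists (of 21 for the latter).

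Direction and call were unaltered in 17 of 22 settings for pyrimidine synthesis and UDP-sugar lists, 13 for S phase, 14 for G2/M and B cell activation, 15 for age-associated, 18 for follicular, 19 for secretory, 20 for plasma cell and ribosomal protein and 21 for platelet lists. They were so in 16 of 21 for pan-B cell and 20 of 21 for mitochondrially encoded lists. Camera with its preset correlation called the erythroid and germinal centre lists in all 22 settings, and both immunoglobulin lists in the 21 that could test them. With an estimated correlation it called none of these 4 lists (adjusted p = 0.104, 0.784, 0.784 for variable segments and 0.771 for constant regions). Depth did not order the groups (5.81 to 18.8 in the controls and 10.6 to 28.6 in UMPS_BKO, in units of 1000000 reads).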

Other observations

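The random-set test of the IgG genes and the counts over other splits were set down before their results were seen, and the other tests in this part, the library measures and the sets of neighbouring genes included, were chosen after.

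Fewer variable segments were read in UMPS_BKO replicates 2, 3 and 4 than in any control, while replicate 1 lay within the controls. Variable segments above 0 numbered 68, 197, 175 and 147 in the controls and 149, 14, 37 and 15 in UMPS_BKO replicates 1 to 4 (exact permutation p = 0.0857). The 5 most abundant segments held 35.3%, 23.1%, 18.5% and 28.0% of variable segment TPM in the controls and 25.8%, 66.8%, 48.0% and 69.7% in UMPS_BKO (exact permutation p = 0.0857; adjusted p = 0.166 for both measures). IgA did not follow IgG: Igha per 100 TPM of summed IgG genes was 25.7, 10.1, 9.29 and 15.7 in the controls and 153, 716, 307 and 96.2 in UMPS_BKO (exact permutation p = 0.0286, adjusted p = 0.157 over 33 library measures).

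Of 14 red cell genes other than globins, 13 had fitted differences above 0, 0 passed over all genes in limma (5 at an unadjusted p under 0.05) and 9 had overlapping groups. Epor, the erythropoietin receptor, stood at −0.55 ± 1.01 (SE; adjusted p = 0.736). It turned to 0.39 with quantile normalization, to 0.34 with array weights and to 0.86 with the pan-B cell mean as covariate. Without UMPS_BKO replicate 2 or 4 it turned to 0.015 in each case, and without the liver- and muscle-marked libraries to 0.21. Alas2, the first enzyme of heme synthesis in red cell precursors, differed by 4.33 ± 0.96 (SE; limma, adjusted p = 0.152) and Slc4a1, the red cell anion exchanger, by 3.61 ± 1.01 (adjusted p = 0.277), with all 4 UMPS_BKO libraries above all controls for each.

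The fall of A530040E14Rik (ENSMUSG00000072109, GRCm38 chromosome 1, 85105946 to 85114035), singled out after its values were seen, was −4.70 ± 0.76 (adjusted p = 0.0330; lower in 4 of 4 libraries). The call ended after scaling by the median of ratios (−3.98, adjusted p = 0.135), after quantile normalization (−3.81, 0.0797), with a pseudocount of 0.1 (−6.41, 0.277) and with no filter (−4.70, 0.300). It also ended without control replicate 2 (−4.62, 0.127), 3 (−4.54, 0.177) or 4 (−4.63, 0.120) and without UMPS_BKO replicate 2 (−4.30, 0.118), 3 (−5.15, 0.0583) or 4 (−5.04, 0.0510). The adjusted p ranged from 0.00589 to 0.769 over all settings. Its neighbours Sp110 (17.1, 46.0, 53.2 and 48.2 TPM in the controls, 1.94, 0.0150, 9.24 and 2.47 TPM in UMPS_BKO) and Sp140 (11.0, 53.1, 87.8 and 43.2 TPM in the controls, 0, 5.44, 11.4 and 3.53 TPM in UMPS_BKO), which encode nuclear body proteins, had log2 differences of −3.60 ± 0.77 (adjusted p = 0.144) and −3.19 ± 0.87 (adjusted p = 0.277). A530032D15Rik (85083069 to 85109853), which overlaps A530040E14Rik in position, stood at 0.26 ± 0.58. As the strand setting is not known, reads of the overlapping genes may not be told apart.

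The first pattern weighed is the rise of erythroid transcripts. Scaling by ribosomal RNA-like and mitochondrial features is argued against by its direction. On average they took more of TPM in UMPS_BKO (47.5% against 27.8%, and 15.8% against 7.89%), which lowers other genes there. Their removal enlarged the difference in the erythroid share from 4.88 to 5.65 log2 units (exact permutation p = 0.0286). That change follows from these shares and is no separate test. A smaller share of B cells that lifts every other cell type alike is argued against by the erythroid minus T cell means, which differed by 4.06 log2 units with no overlap of the groups (exact permutation p = 0.0286). The T cell list alone stood for the other cell types here. The shifts of both lists had been seen when they were compared. RNA of red cell precursors or reticulocytes in the isolates remains a candidate explanation, since all 14 non-globin genes of the list lay above the median of all genes, by a median of 2.53, and 5 had groups that did not overlap. Whether more of these cells arose in UMPS_BKO spleens or more passed through the isolation was not tested, and the isolation method is not given in the sources used here.

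The second pattern is the lower level of IgG transcripts. Dilution of B cell RNA by other RNA would lower IgG and pan-B cell genes alike, whereas IgG per TPM of pan-B cell genes changed by a fold of 0.0455 with no overlap (exact permutation p = 0.0286, adjusted p = 0.157). On the log2 scale this was −4.46, and −3.72 without UMPS_BKO replicate 2 and −3.83 without control replicate 2 (exact permutation p = 0.0286 and 0.0571). Without control replicate 3 it was −4.26, and without UMPS_BKO replicate 1 it was −5.08 (exact permutation p = 0.0571 and 0.0286). Loss of transcripts at random in libraries with few detected genes was set against 10000 random sets of 4 genes matched on mean level. In 0% of the sets was the median as low, the lowest being −1.75 where the IgG genes had −4.79. The sets were drawn gene by gene, whereas constant region genes varied together (estimated correlation 0.83). The test therefore cannot exclude a loss that strikes such genes together. An equal loss of antibody-secreting cells of every class is argued against by IgA per IgG, which changed by a fold of 17.1. A lower share of class-switched IgG cells after Umps deletion is a hypothesis that may account for this. Counts of switched cells would be needed to decide it and were not used here, and differences in cell isolation or in the animals stay open as untested.

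The third pattern is the low level of A530040E14Rik, Sp110 and Sp140, of which A530040E14Rik alone passed the test. A lower type I interferon response cannot be told apart from an effect on the locus. The mean of these 3 genes, Gm7609 and Sp100 (the last at −1.89 ± 0.83 with overlapping groups, adjusted p = 0.283) minus the interferon list mean differed by −1.99 log2 units with no overlap. These 5 genes were picked for their low values. The 6 tested neighbours of A530040E14Rik taken by position differed by −0.65 with overlapping groups (exact permutation p = 0.314). They are A530032D15Rik, which overlaps A530040E14Rik in position, and the 5 genes that follow. Fewer B cells cannot be told apart either. Relative to the pan-B cell mean the 5 genes differed by −1.40 with overlapping groups (exact permutation p = 0.0857). UMPS_BKO replicates 1, 2 and 3 lay at −6.38, −4.80 and −3.64, below the controls (−3.32 to −2.87), and the muscle-marked replicate 4 at −2.95. The 6 neighbours differed by −0.06 (exact permutation p = 0.914). A strain or passenger variant over the locus cannot be told apart from these. The 5 tested genes that follow A530040E14Rik (85199613 to 85709998) ranked 26 of 10464 such windows, but the window was set after their values were seen and leaves out A530032D15Rik. Windows of B cell and MHC class II genes ranked lower still, such as that of H2-Ab1 and H2-Aa at rank 4. Sharing of reads between related copies in this gene family was not tested.

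Other splits of the 8 libraries into 4 and 4 did not exclude chance for the counts of calls. At least 4 genes in one direction, and likewise at least 10, were called in 2 of the 35 splits, the real one included, and the highest of the other splits called 2365 in one direction. That split sets control replicate 1 with UMPS_BKO replicates 2, 3 and 4, and so places 6 of the 8 libraries as the genotype does. It points to a structure of the samples that overlaps with the genotype, and the calls between genotypes were not separated from it. The median-of-ratios factors of those libraries were 0.788, 0.499, 0.805 and 0.683, against 1.90, 2.15, 1.44 and 1.19 in the others. As many lists as the 15 called were called in 6 of the 35 splits, and the highest of the other splits called 17. The median over the other splits was 11 lists, and the fewest in any split was 6. Camera calls at the preset correlation were therefore common in groupings other than the genotype.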
